A study of Oncorhynchus mykiss with 2 samples.

How the data were processed

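The series holds 2 samples of male rainbow trout: type A spermatogonia and testicular somatic cells, with 1 array each. Per the labels, cells came from fish carrying a vasa-promoter green fluorescent protein transgene and were isolated by fluorescence-activated cell sorting, total RNA was extracted on columns with DNase digestion, and 25 ng of RNA per sample was labelled with Cy3. Samples were grouped by the cell type in their labels. The labels do not say how many fish or sorts went into a sample.

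The deposited scanner output gives an intensity for each spot on a linear scale, written by Agilent Feature Extraction 10.7.3.1 per the file headers, for custom array design 034067. The submitters' processing notes name Agilent Feature Extraction 10.7. The processed signal in these files is the spot intensity after background subtraction and detrending within the array by that software, and it is not normalized between arrays, per the file headers. The headers place both arrays on 1 slide and in 1 scan. The authors also deposited a table of processed values, made from the same arrays, which was taken as log2 from its values because its scale is not given in the sources used here. Each column followed the log2 signals of its own array with slopes of 1.02 and 0.983 and r of 0.9997 on each array. Its columns have the same median (6.97) and nearly the same distribution, as quantile normalization gives, but the step itself is not given in the sources used here. Its direction and scale were thus settled from the scanner values, and it was used as an alternative.

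Each array has 105072 spots, of which 1325 are controls and were left out. The other 103747 spots belong to 55928 probes. Contig probes have 2, 3, 12 or 13 spots, and single-read probes have 1. Spots marked as non-uniform or population outliers on either array were dropped (1104 marked in spermatogonia and 1198 in somatic cells), which left out 12 probes entirely. The log2 processed signal was averaged over the spots of a probe, and the 75th percentile of the array's non-control spots (769 in spermatogonia, 497 in somatic cells) was subtracted on the log2 scale. A probe counted as detected when more than 50% of its spots were well above background by the software's flag. Of 300 negative control spots, 4 (1.33%) carried this flag on each array. The lowest signal of a detected probe was 19.7 in spermatogonia and 13.8 in somatic cells.

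The difference was taken as spermatogonia minus somatic cells. For a probe detected on 1 array alone, the brighter level was set against the higher of the lowest detected level on the other array and the probe's own level there, and the result is a bound ("at least"). A probe was counted at a difference of at least 4-fold (2 in log2). With 1 array per group, no p-value, standard error or count of significant genes was computed. The calculation was tested on simulated arrays of 55916 probes made from the measured levels and spot noise. All 50 probes set 3 higher in log2 and all 50 set 3 lower were called in the right direction. None of the 100 probes set 1 apart, 50 each way, and none of the 55716 unchanged probes was called. The simulated noise was the median spot SD alone, without differences between samples or labelling reactions. These counts therefore check the calculation and give no rate of false calls for the measured arrays.

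The samples, the comparison, the alternatives, 19 gene lists and the rule for named genes were fixed before the data were examined. The rule named vasa, the members of each list with the largest differences, the 6 genes with the largest difference each way among those detected and unsaturated on both arrays with a brighter level at or above the median of detected probes, and the brightest genes of each array alone. The gene table used here (72772 genes of assembly USDA_OmykA_1.1, used for names alone) matched 0 probe or sequence names. The gene lists were therefore not computed, vasa could not be reported, and the rule was applied to probes in its part on largest differences, with 2 probes named each way because probe numbers carry no gene identity.

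Alternatives were normexp background correction (offset 50) followed by 75th percentile or quantile scaling, scaling to the median of detected probes, to spike-in controls or not at all, a loess fit of the difference on signal (span 0.7), the authors' value table, filters on dim, saturated and outlier spots, thresholds of 2-fold and 8-fold, and the less strict detection flag. Normexp was planned on mean spot signals, which the scanner files used here do not hold, and was run on median spot signals instead. That change, a rule that all spots of a probe be well above background, the wider choice of spike-in probes, and the grouping of contigs by name were chosen after seeing the data. The spike-in setting used the 5 of 10 spike-in probes with all spots well above background on both arrays, whose mean log2 difference was -0.15 (SD 0.09), against 0.63 for the 75th percentiles. With the rule of more than 50% of spots, 6 probes entered and the mean was -0.12 (SD 0.10). Sets of contigs were compared with 100 shuffles of contigs within 20 bins of mean level.

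Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for background correction, quantile scaling and loess.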

Results

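Transcript levels were measured in 2 cell populations of the immature testis of male rainbow trout. Type A spermatogonia are the undifferentiated male germ cells from which sperm production starts. They were obtained by fluorescence-activated cell sorting from fish carrying a transgene in which the promoter of vasa, a gene active in germ cells, drives green fluorescent protein. Testicular somatic cells, the non-germ cells of the same organ, were isolated from such fish as well. RNA of each population was labelled with the dye Cy3 and hybridised to 1 array, so there were 2 arrays and 1 array per group. The difference between the populations has no replicate check, no test was run, and the number of arrays limits the precision. Both arrays lay on 1 slide, at different positions, so array position and cell population cannot be told apart.

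Most transcripts on the array were measurable in both populations. Of 103747 non-control spots per array, 82613 (79.6%) were well above background in spermatogonia and 82287 (79.3%) in somatic cells. The median spot signal was 197 in spermatogonia and 132 in somatic cells, against 5.05 and 3.83 for 300 negative control spots. No spot was saturated. After spots marked as outliers by the scanner software were removed, 55916 probes remained. Of these, 42580 (76.1%) were detected in spermatogonia and 42387 (75.8%) in somatic cells. Both populations shared 37959 detected probes, and 8908 probes were detected in neither. The array names its probes only by custom probe numbers and by the contigs or single sequence reads they were made from, and none of these names matched the gene table used here. Probes are therefore given by their numbers, and genes and pathways could not be assigned.

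The comparison of the 2 populations asked which transcripts mark type A spermatogonia against their somatic neighbours in the immature testis. Of the 47008 probes detected on at least 1 array, 5841 (12.4%) were at least 4-fold higher in spermatogonia and 7083 (15.1%) were at least 4-fold higher in somatic cells. These counts include probes detected on 1 array alone. Their level was set against the higher of the lowest detected level on the other array and their own level there. Probes detected on 1 array alone made up 1622 of the probes higher in spermatogonia and 2345 of those higher in somatic cells. Among the 37959 probes detected in both populations, 17771 (46.8%) differed by less than 2-fold. The median difference over these probes, spermatogonia minus somatic cells, was 0.03 in log2 with an SD of 1.85. Across these probes, which are not independent replicates, the levels of the populations correlated with a Pearson r of 0.669 and a Spearman rho of 0.624.

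The balance between the directions depended on how the arrays were scaled and corrected for background. With each array scaled to its 75th percentile, 45.2% of the probes at least 4-fold apart were higher in spermatogonia. With the same scaling after normexp background correction of median spot signals, the share was 33.4% (2194 higher, 4384 lower). It was 68.2% (10398 higher, 4849 lower) without scaling, and 72.6% (11748 higher, 4430 lower) with scaling to the spike-in control transcripts. Relative to the 75th percentile, the median difference shifted by -0.14, 0.63 and 0.78 in log2 under these settings. It shifted by -0.12 with an intensity-dependent loess fit and by 0.15 in the authors' value table. Directions of small differences are therefore given relative to the 75th percentile of each array.

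**Figure D1:**
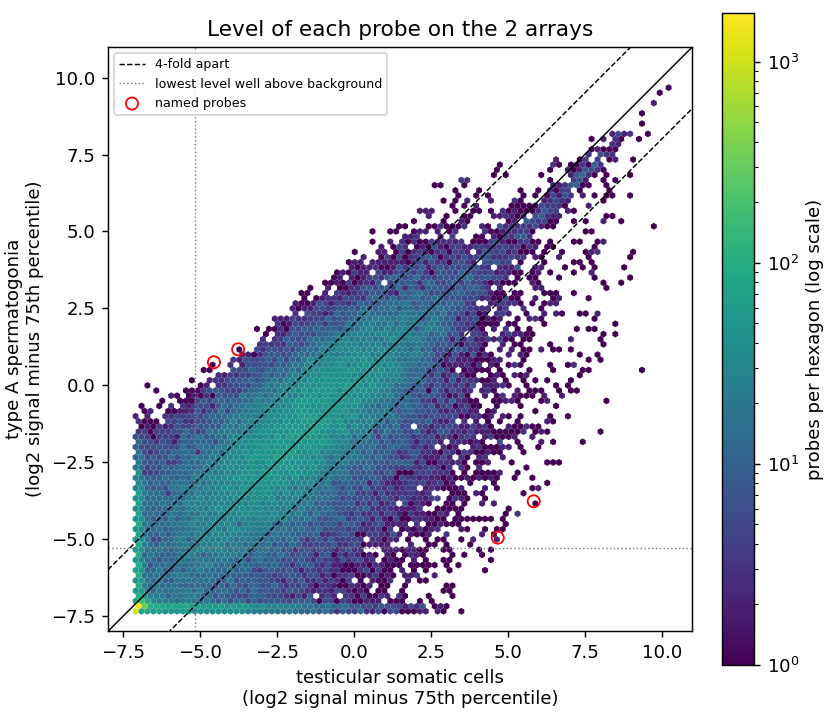
Level of each probe in testicular somatic cells (horizontal) and type A spermatogonia (vertical), as log2 signal minus the 75th percentile of its array, with colour for the number of probes per hexagon on a log scale. Solid and dashed diagonals mark equal levels and 4-fold differences, dotted lines the lowest level well above background (-5.29 in spermatogonia, -5.17 in somatic cells), and red circles the 4 probes named in the text, which differ by 5.30, 4.94, -9.63 and -9.61.

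Differences of at least 32-fold were more frequent towards somatic cells than towards spermatogonia under each scaling tried, whereas the order at smaller folds turned with the scaling. Among probes detected in both populations, 10512 were at least 2-fold higher in spermatogonia and 9676 at least 2-fold higher in somatic cells. At 8-fold the counts were 1270 and 2477, and at 16-fold they were 211 and 1271. At 32-fold, 1 probe was higher in spermatogonia and 673 were higher in somatic cells. The 32-fold counts were closest under spike-in scaling, at 114 and 371. With that scaling the order was the opposite at 8-fold (3311 and 1479) and at 16-fold (927 and 759), and without scaling it was the opposite at 8-fold (2776 and 1637) but not at 16-fold (764 and 825).

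Among probes detected on both arrays, the largest difference towards spermatogonia was that of probe CUST_25214_PI425928308, made from contig YGL02.20298.C1. Bounds of 2 probes detected in spermatogonia alone lay above it. Its log2 level was 0.75 in spermatogonia and -4.56 in somatic cells, a 39.4-fold difference (5.30 in log2). The SD of this difference over its 2 spots, which are repeats on 1 array and not biological replicates, was 0.027. The somatic cell level of this probe lay near the lowest detected level on that array (-5.17), so the fold depends on a signal near the detection limit. Probe CUST_6952_PI425928308 (contig YGL02.4253.C1) came next among probes detected on both arrays, with levels of 1.17 and -3.77 and a 30.6-fold difference, and the SD over its 3 spots was 0.017. It lay below the bounds of 8 probes detected in spermatogonia alone. Towards somatic cells, the bounds of 3 probes detected there alone were further from 0 than any difference measured on both arrays. Among the latter, probe CUST_1929_PI425928308 (contig YGL02.983.C1) had the largest difference, with a level of 4.67 in somatic cells and -4.96 in spermatogonia. That is a 791-fold difference (-9.63 in log2), with an SD of 0.508 over 3 spots. The spermatogonial level of this probe also lay near the lowest detected level on its array (-5.29), so this fold has the same limit. Probe CUST_11352_PI425928308 (contig YGL02.7597.C1) had levels of 5.84 in somatic cells and -3.77 in spermatogonia, a 784-fold difference with an SD of 0.235. Over the alternative settings the log2 differences ranged from 3.42 to 6.08, from 3.51 to 5.71, from -9.84 to -7.08 and from -9.80 to -7.80 in this order. The directions held while the sizes moved. Probes picked for the largest differences were unlikely to reverse when the same arrays were processed otherwise. For each named probe, the smallest size of the difference came under normexp. The ranks of these probes among probes detected on both arrays did not hold under normexp either. By construction, the normexp offset of 50 lowers differences that rest on a dim signal, as those of the named probes do. How much of the change in size and rank it explains was not tested. With 75th percentile scaling after normexp the probes named towards spermatogonia ranked 133 and 93, and those named towards somatic cells 25 and 7; with quantile scaling the ranks were 114, 100, 25 and 7.

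Repeat spots gave an estimate of the measurement error within an array. Spots marked as outliers had been dropped beforehand, so the estimate can be too small. Over 20966 probes with at least 2 spots and detection on both arrays, the median SD of the log2 level over repeat spots was 0.057 in spermatogonia and 0.056 in somatic cells. For the difference between the arrays, taken spot by spot, the median SD over repeat spots was 0.068 in log2, and its 95th percentile was 0.294. Of the 12924 probes at least 4-fold apart, 7307 had at least 2 spots and 5617 had 1 spot. This spread leaves out differences between fish, sorts and labelling reactions.

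Detection in 1 population alone was about as frequent in either. Spermatogonia alone gave 4621 detected probes and somatic cells alone gave 4428. These probes were dim, with a median log2 level of -3.56 in spermatogonia for the first group and -3.10 in somatic cells for the other. With the scanner software's less strict flag, 2740 and 3132 probes were detected in 1 population alone, so the order of the counts turned with the flag.

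Probes made from contigs and from single reads differed in how often they were higher in spermatogonia. Of 28578 contig probes, 25100 (87.8%) were detected on at least 1 array, against 21908 (80.1%) of 27338 single-read probes. Among the detected ones, 3549 contig probes (14.1%) and 2292 single-read probes (10.5%) were at least 4-fold higher in spermatogonia. At least 4-fold higher in somatic cells were 3765 contig probes (15%) and 3318 single-read probes (15.1%). Contig probes had the larger share higher in spermatogonia under each setting in which it was recomputed, from 4.66% against 3.39% at an 8-fold threshold to 32.2% against 25.9% at a 2-fold threshold. For the shares higher in somatic cells, the order turned with the setting. Contig probes had 9.92% against 8.64% with normexp and 75th percentile scaling, but 27.6% against 29.7% at a 2-fold threshold. Contig probes were also brighter among those detected on both arrays, with median log2 levels of -0.80 against -1.47 in spermatogonia and -0.93 against -1.42 in somatic cells.

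**Figure D2:**
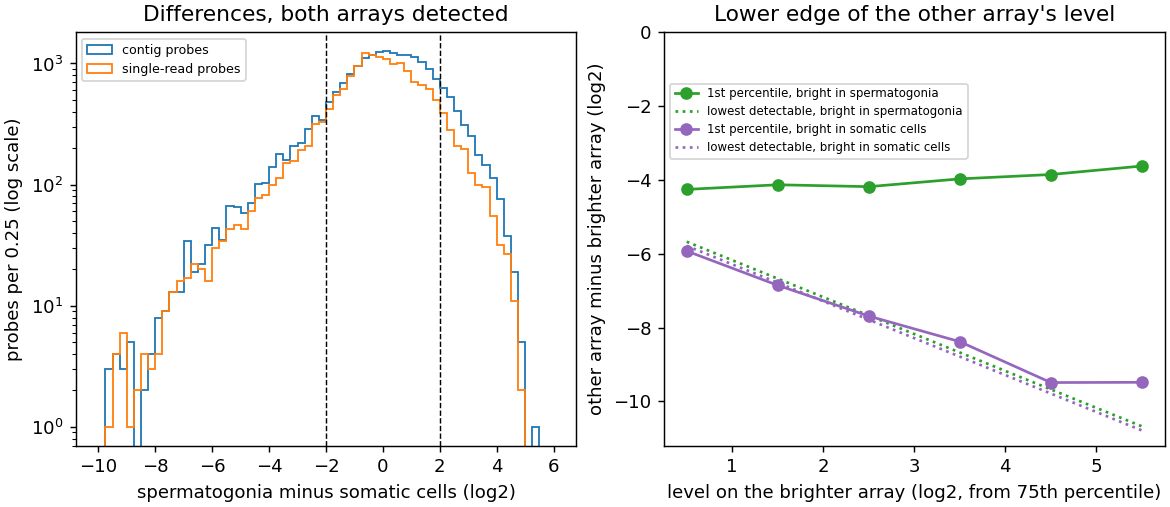
Left, number of probes per 0.25 of log2 difference (spermatogonia minus somatic cells, log-scaled counts) among probes detected on both arrays, for contig and single-read probes, with dashed lines at 4-fold. Right, first percentile of the log2 difference (other array minus brighter array, probes not detected on the other array at their bound) against the level on the brighter array, with dotted lines for the lowest detectable level; for probes bright in spermatogonia it lay between -4.26 and -3.62, and for probes bright in somatic cells between -9.49 and -5.93, close to the lowest detectable level below a level of 5.

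Pooled over sets, contigs whose names share a number differed less from one another than contigs of like level shuffled between sets did. This grouping was chosen after the names were seen, and what the shared number stands for is not given in the sources used here. The 2911 sets with at least 2 detected members held 7451 contigs. The pooled SD of the difference within these sets was 1.03 in log2, against 2.07 to 2.13 when contigs of like level were shuffled between sets 100 times. This did not hold for each set. Among sets with at least 10 detected members, the SD ran from 0.13 to 2.63, and the largest set, of 70 contigs, had 2.06. Whether probes of a set share sequence or bind the same transcripts was not examined, so the members of a set were not counted as separate measurements.

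The 25 sets with at least 10 detected members held 574 contigs. A set of 10 contigs had a median difference of 3.21 towards spermatogonia, and 8 of its 10 members were at least 4-fold higher there. A set of 15 contigs (median 1.97) and a set of 31 contigs (median 1.55) were higher in spermatogonia for all members, with 7 and 9 of them at least 4-fold higher. Towards somatic cells, a set of 17 contigs had a median of -2.75 with 14 members at least 4-fold apart, and a set of 10 contigs had a median of -2.28 with 5 such members. A set of 19 contigs (median -1.82) was higher in somatic cells for all members, 3 of them by at least 4-fold. The medians of these 6 sets, picked as the largest each way, kept their sign under each alternative in which sets were recomputed, but not their size. The median of 1.97 fell to 0.67 at its lowest, that of -2.75 reached -1.97 and that of -2.28 reached -1.45 at their closest to 0. With spike-in scaling, 0 sets had a median at least 4-fold higher in somatic cells, against 2 as given here. Towards spermatogonia, 3 sets had such a median with that scaling, against 1 as given here. Over all 25 sets, 8 medians lay above 0 and 17 below, but with spike-in scaling these counts were 15 and 10.

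**Figure D3:**
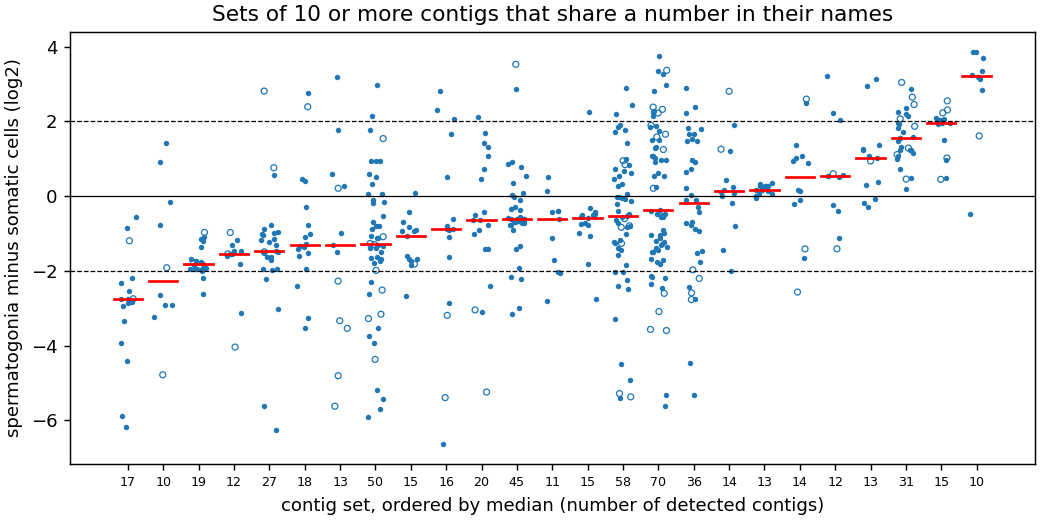
Log2 difference (spermatogonia minus somatic cells) of each contig in the 25 sets of at least 10 detected contigs that share a number in their names, ordered by set median (red lines), with the number of contigs below each set. Filled points were detected on both arrays, open points are bounds from 1 array, and dashed lines mark 4-fold; medians run from -2.75 to 3.21, and those of the sets ranked 11 to 18 change sign under at least 1 other scaling.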

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

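The test of neighbouring spots below was chosen after the probe had stood out, with its prediction written before its result was seen. Of the control probes outside the comparison, 3 were well above background at all of their spots on 1 array and at none on the other. Control probe ETG10_195139 had a median signal of 136.65 in somatic cells and 5.14 in spermatogonia, a log2 difference (spermatogonia minus somatic cells, relative to the 75th percentiles) of -3.42 or further from 0. The 20 spots of this probe spanned 490 rows and 194 columns, with somatic cell signals from 128 to 151, which argues against a single local mark on the slide. A mark would also brighten the spots next to them. The 52 adjacent spots that were not well above background in spermatogonia had a median somatic cell signal of 6.82. For all such spots on the array it was 8.45. With the probe's spots so far apart, this outcome was likely in advance and adds little. What this probe binds is not given in the sources used here, so a transcript of the somatic cells and a difference between the labelling reactions both stay open, and no biological explanation was tested.

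Control probe DCP_20_7 had a median signal of 52.04 over its 2 spots in spermatogonia and 14.3 in somatic cells, at least 2.35-fold higher in spermatogonia. Control probe DCP_20_9 had a median signal of 34.69 over 2 spots in spermatogonia and 12.7 in somatic cells. It was at least 1.63-fold higher in spermatogonia on the same scale.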

How the results depend on the processing

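The normexp runs, the wider choice of 6 spike-in probes and the rule that all spots be well above background were chosen after the data were seen; the other settings were planned. Against 5841 probes at least 4-fold higher in spermatogonia and 7083 in somatic cells, normexp gave 2194 and 4384 with 75th percentile scaling and 2740 and 3863 with quantile scaling. No scaling gave 10398 higher in spermatogonia, and spike-in scaling gave 11748 and 4430, or 11543 and 4494 with 6 spike-in probes. These settings add a constant (0.63, 0.78 and 0.75 in log2) to each difference, which by construction moves the counts apart. The offset of normexp lowers differences of dim probes by construction; how much of its change this explains was not tested. By construction, a 2-fold threshold gave more probes (13767 and 13426) and an 8-fold threshold fewer (1913 and 3886). With the less strict detection flag, 2740 probes were detected in spermatogonia alone, against 4621; the cause was not tested. These are the 14 recomputed counts that moved by over 1.5 times, and the other 22 stayed within it. No direction of a named probe reversed, which was likely beforehand for probes picked for the largest differences. Counts at 32-fold, 1 and 673 as reported, ranged from 0 to 114 towards spermatogonia and from 287 to 736 towards somatic cells. Leaving out saturated probes moved nothing, since no spot was saturated. Alternatives on gene lists, on the mean of a gene's probes and on symbol matches were not run, because no probe carried a gene name. Signal over background limits dim probes: 1622 and 2345 of the counted probes were not well above background on the other array and are bounds.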

Other observations

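The test of carried-over RNA below was chosen after the result was seen, as was the grouping of contigs by name. Some contig sets held members that differed in opposite directions. Of the 25 sets with at least 10 detected contigs, 12 held both members at least 4-fold higher in spermatogonia and members at least 4-fold higher in somatic cells. The set with the most members, 70 contigs, had 12 of the first kind and 11 of the other. Over all detected contig probes, 14.1% were of the first kind and 15% of the other, and the largest set lay near these shares. Large sets were therefore likely to hold both kinds, and whether more sets did so than shuffled ones was not tested. By contrast, a set of 13 contigs had a median of 0.18 with all members between -0.05 and 0.35. The number in a contig's name was related to its mean level (Spearman rho -0.29 across 25100 contigs) and barely to its difference (rho 0.03).

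The probes brightest in spermatogonia were all detected in somatic cells, whereas the reverse did not hold. Of 7028 probes with a log2 level of at least 1 in spermatogonia, 0 were undetected in somatic cells. Of 7622 probes as bright in somatic cells, 182 (2.39%) were undetected in spermatogonia.

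Differences of at least 32-fold were much rarer towards spermatogonia: 7 of the 13104 probes bright enough to show one, against 1116 of 14088 (7.92%) towards somatic cells. These counts include bounds of probes detected on 1 array alone. Without the bounds, they were 1 and 673. A background floor of the somatic cell array would make the lowest somatic level, relative to the spermatogonial one, fall by about 1 per unit of spermatogonial level, but the slope was 0.12, which argues against it. Scaling as the whole cause is argued against by the ratio of such probes towards spermatogonia to those towards somatic cells, among probes detected on both arrays, which reached at most 0.3073, with spike-in scaling (114 and 371), although at 16-fold that scaling turned the order (927 and 759). Spermatogonial RNA carried into the somatic cell sample could set such an edge, and so could low expression of these genes in somatic cells themselves; these cannot be told apart, because no probe is named as a germ cell marker and the ratio of the shares (0.0067) only restates the pattern. Sorting on the reporter would remove germ cells from the somatic sample as far as its gate separated them. The tenth largest difference, with bounds counted, would limit carried-over RNA to 3.27% of that sample. This limit ranged from 1.90% with spike-in scaling to 6.11% with normexp and 75th percentile scaling. The normexp offset of 50 raises dim somatic signals and so this limit by construction, and how much of the rise it explains was not tested.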
